A study of Homo sapiens with 6 samples.

How the data were processed

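Total RNA of CAL27 cells was sequenced in 6 libraries, 3 from cells given a control plasmid and 3 from cells overexpressing RBM24. Per the labels, RNA was extracted with Trizol and treated with DNase, and the libraries were read as 150-nt pairs on a NovaSeq 6000. The columns marked NC were read as the control plasmid libraries and those marked OE_RBM24 as the overexpression libraries; the labels do not say whether the replicates were separate cultures. Per the submitters' processing notes, reads were aligned to GRCh38 with HISAT2, whose version is not given in the sources used here. The gene counter, the annotation release, the library kit and whether counting was stranded are not given there either. The deposited count table holds raw whole-number counts for 32353 genes, made by the authors from those alignments. The deposited FPKM table holds 31513 genes, with values that the authors had divided by gene length and by a library total and rounded to 2 decimals; that total is not exactly the sum of the deposited counts. The design text also speaks of alternative splicing and of iRIP-seq, neither of which was analysed here, since gene-level counts hold no splice junctions and no bound fragments.

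Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given, which left 17887, and libraries were scaled with TMM factors, which lay between 0.976 and 1.02. The 2 groups were compared with a quasi-likelihood F test with a model of group alone, which leaves 4 residual degrees of freedom. P-values were adjusted with Benjamini-Hochberg and called at an adjusted p under 0.05. The biological coefficient of variation was 0.0645. A log2 fold change is RBM24 over control plasmid throughout; CPM values divide each gene's count by the TMM-scaled library total, with SD over 3 libraries. Libraries separate when every value of one group lies above every value of the other, for which chance gives 10% at 3 against 3; the smallest exact p of a rank test is then 0.1, so no such test was used for single genes.

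The tested genes include 13789 protein-coding ones. The chi-square per gene between pairs of libraries lay between 4.20 and 30.1, so no library was a copy of another. Gene coordinates come from GENCODE 29 on GRCh38, a release that need not be the one the authors used: 17627 of the 17887 gene identifiers (98.5%) are in it, 4041 of them in the same version, and 14810 with the same symbol. Of 609 tested list members, 24 overlap on the same strand a tested gene with a higher level, so that their counts depend on how the counter shared reads.

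The study's comparison, its tests, the gene lists and the rule for naming genes were fixed before the data were examined. The 28 lists hold 671 genes, with 6 in more than 1 list, and include pro-apoptotic, anti-apoptotic, interferon-stimulated, antigen presentation, inflammatory NF-kB, G1/S replication, G2/M mitosis, replication-dependent histones, basal keratinocyte, keratinocyte differentiation, epithelial adhesion, mesenchymal and invasion, ATF4 stress response, ER chaperones, heat shock, hypoxia and glycolysis, cholesterol synthesis, immediate early, NRF2 targets, splicing regulators, muscle, fibroblast, immune and endothelial markers, mitochondrial-encoded, nuclear oxidative phosphorylation and ribosomal proteins. Lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, again with the correlation estimated from the data, and with fry, each adjusted with Benjamini-Hochberg over the 28 lists. Members were also adjusted over their list alone. Named genes are RBM24; the 12 with the largest increase and the 12 with the largest decrease among those called, with a mean log2 CPM of at least 2, libraries that separate and a protein-coding gene type; up to 4 tested members of each list with the smallest p; and a fixed panel (among them CDKN1A, TP63, MYC, CCND1, EGFR, RBM38, BCL2, MCL1 and BAX). Some of the genes this rule names, and 1 of the lists, are not reported here.

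Alternatives were DESeq2 size factors or upper-quartile factors in edgeR, total counts only, no low-count filter, a mean count of at least 50, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with the count filter and on log2(FPKM + 1) without, the replicate number as a block, counts thinned at random to the smallest library, each library left out in turn, RBM24 left out, a log2 fold change of at least 1 and an adjusted p under 0.01. A fit on protein-coding genes only was added after the data were seen. Principal components used log2 CPM with a prior count of 2. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

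The pipeline was tested on simulated counts with the dispersion of the data and 17887 genes. Of 50 genes changed by each fold, it recovered 58% at 1.25-fold, 60% at 1.5-fold, 82% at 2-fold and 100% at 4-fold; 17 of 167 calls (10.2%) were false, against the 5% aimed at. Lists were simulated separately on 17656 genes. A list of 25 genes shifted 1.3-fold was recovered, and 0 of 28 unchanged lists were called by camera. Simulated genes were drawn independently, whereas the correlation estimated for the real inflammatory list was 0.785. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Library totals lay between 53558773 and 68804210 counts, and the 10 most abundant genes took 8.62% to 9.69% of them. At this depth a gene at 1 CPM has more than 50 counts in each library.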

Results

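Gene expression was compared between 2 groups of CAL27 cells, an established human cell line of tongue squamous cell carcinoma. The control group had been given a control plasmid (3 libraries), and the other group overexpressed RBM24 (3 libraries), an RNA-binding protein best known as a regulator of alternative splicing in heart and skeletal muscle. The control libraries held 56105482, 55139782 and 62156648 gene counts, and the RBM24 libraries 68804210, 53558773 and 60589183. Of 32353 genes in the count table, 17887 passed the filter on low counts and were tested, and 13789 of these were protein-coding. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. On the main axis of a principal component analysis, which held 33.0% of the variance, control library 1 stood apart at -33.4. The other control libraries lay at -4.95 and -0.0363 and the RBM24 libraries between 9.28 and 15.4. Control library 1 also stood out in genes of small structured RNAs, whose share of its raw counts was 7.19-fold the mean of the other 5 libraries.

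The overexpressed gene itself came first, since it checks the labels. RBM24 (ENSG00000112183.15, GRCh38 chromosome 6, 17281346 to 17293875, plus strand) stood at 2.93 ± 0.576 CPM (SD, n = 3) in the control libraries and at 120 ± 8.89 (SD, n = 3) with overexpression. The raw counts were 129, 159 and 220 in the control libraries and 8651, 5918 and 7648 in the RBM24 libraries. RBM24 was thus 40.5-fold higher in the fit, and every RBM24 library lay above every control library, a log2 fold change of 5.34 (SE 0.0995; edgeR, Benjamini-Hochberg adjusted p = 2.16e-15). In the deposited FPKM values it stood at 0.783 ± 0.175 and 32.7 ± 2.38 (SD, n = 3 each). Counts per gene do not separate the plasmid's transcript from that of the cells' own gene.

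The study asked how RBM24 changes gene expression in these cells, with apoptosis named in its title. With RBM24, 153 genes rose and 122 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), together 1.54% of those tested. Most changes were small: 28 genes rose and 4 fell at least 2-fold, and the median log2 fold change was 0.38 among the genes that rose and -0.42 among those that fell. The 2-fold counts were unstable: 11 and 4 with a mean count of at least 50, and 9 and 1 by DESeq2. They were 29 and 0 without control library 1, and 31 and 34 without control library 3. All 153 genes that rose and 115 of those that fell had libraries that did not overlap between the groups, as did 18.1% of all tested genes, where chance gives 10%. Genes vary together, so 1 grouping can depart from 10% by chance, and other groupings were not compared in this share. Without RBM24 library 1, 70 genes rose and 31 fell, without RBM24 library 2 the counts were 61 and 29, and without control library 1 or 3 the number that fell was 69 and 198. On the deposited FPKM values, limma on log2(FPKM + 1) called 46 genes higher and 4 lower, on log2(FPKM + 0.1) 57 and 5, and on log2(FPKM + 1) with no filter 15 and 4, while edgeR with no filter on low counts called 305 and 341. Of the 53 genes of the naming rule that passed the test besides RBM24, 28 kept their call without each library in turn, and 39 lost it with limma on log2(FPKM + 1). Scaling by total counts alone gave 223 and 106, so that 67.8% of the calls were higher, against 55.6% with the scaling factors used here.

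The genes that rose most, among those with a mean level of at least 2 on the log2 CPM scale, were led by aldo-keto reductase genes. AKR1C1 (chromosome 10, 4963253 to 4983283), which reduces steroids and reactive carbonyls, rose 3.24-fold from 5.89 ± 0.368 to 19.1 ± 1.32 CPM (SD, n = 3 each), a log2 change of 1.70 (SE 0.0813; edgeR adjusted p = 3.58e-09). Its neighbour AKR1C2 rose by 1.37 on the log2 scale (adjusted p = 5.58e-05). The AKR1C genes are near-identical paralogs, so the split of reads among them is uncertain. GADD45B (chromosome 19, 2476122 to 2478259), a growth arrest and DNA damage response gene, rose from 19.9 ± 2.33 to 43.5 ± 2.11 CPM (SD, n = 3 each; log2 change 1.12, SE 0.0773, adjusted p = 4.66e-07). The interstitial collagenase gene MMP1 rose by 1.01 (adjusted p = 0.00499) and SNAI1, a transcription factor of epithelial-mesenchymal transition, by 0.99 (adjusted p = 1.30e-04). HMOX1, the inducible heme oxygenase, rose from 10.2 ± 0.355 to 17.3 ± 0.729 CPM (SD, n = 3 each; log2 change 0.77, adjusted p = 1.93e-05). This set also held the interferon-induced IFI27 (0.85), the placental alkaline phosphatase ALPP (0.85), the CDK4/6 inhibitor CDKN2D (0.72), the histone H2BC11 (0.65) and the YAP target ANKRD1 (0.61), with adjusted p from 3.50e-05 to 0.0133. Every RBM24 library lay above every control library for all of these genes, which the naming rule required. ALPP shares sequence with the neighbouring ALPG, so its reads are uncertain too.

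**Figure D1:**
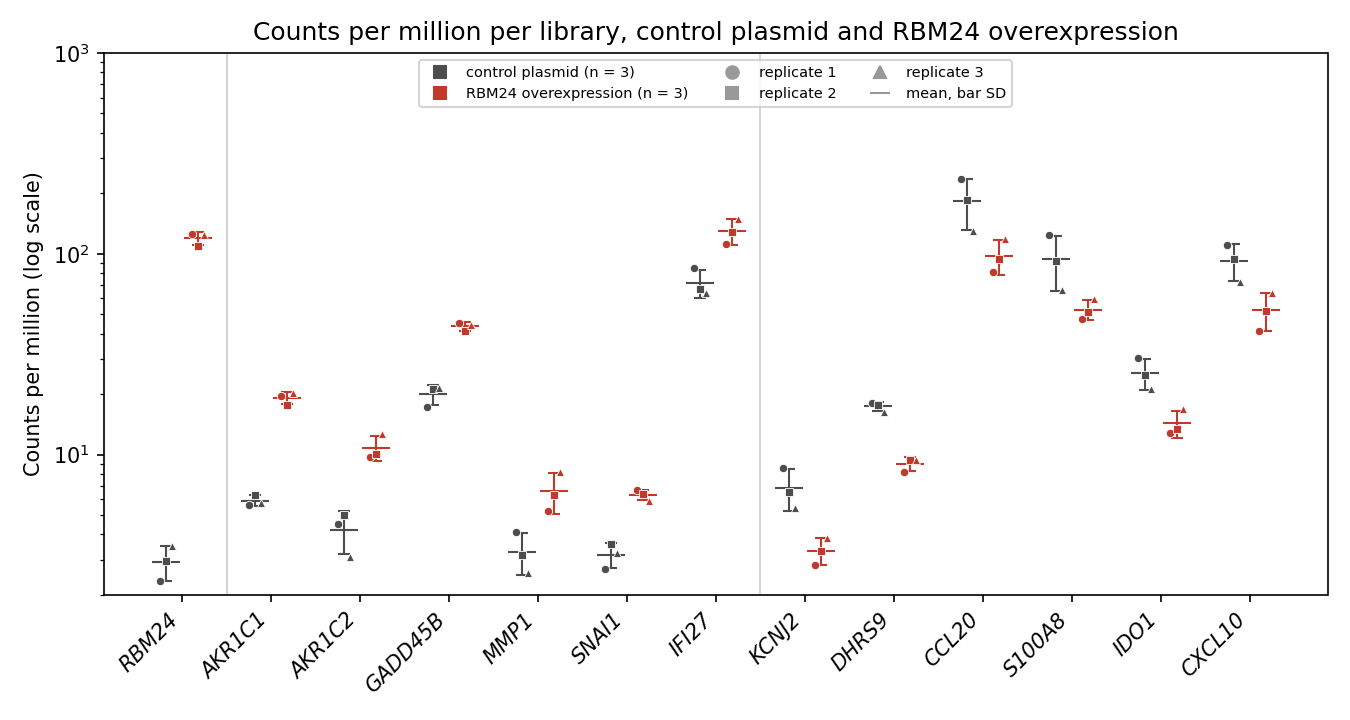
CPM (log axis) in each of the 6 libraries for RBM24, the 6 genes of the naming rule with the largest increases and the 6 with the largest decreases. Points are libraries, with shapes for the replicate number, and horizontal marks and bars are the mean and SD of 3 libraries; RBM24 went from 2.93 to 120 CPM and CCL20 from 184 to 97.6.

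Of the 12 genes that fell most by the naming rule, CCL20, CXCL10, CXCL11, CSF3 and CXCL3 were members of the list of inflammatory NF-kB genes fixed before the data were examined. CCL20, a chemokine for CCR6-bearing cells (chromosome 2, 227805739 to 227817564), fell from 184 ± 52.1 to 97.6 ± 19.0 CPM (SD, n = 3 each), a log2 change of -0.91 (SE 0.153; edgeR adjusted p = 0.00604). The interferon-inducible chemokines CXCL10 and CXCL11 changed by -0.81 (adjusted p = 0.00577) and -0.71 (adjusted p = 0.00622) on the log2 scale. IDO1, the tryptophan-degrading dioxygenase, changed by -0.83 (adjusted p = 0.00113), the calprotectin subunit gene S100A8 by -0.83 (adjusted p = 0.00862), the epithelial cytokine gene IL17C by -0.81 (adjusted p = 0.00622) and the ubiquitin-like UBD by -0.68 (adjusted p = 0.00611). The set also held the inward rectifier potassium channel gene KCNJ2 (log2 change -1.04, edgeR adjusted p = 0.00143) and the retinol dehydrogenase gene DHRS9. DHRS9 fell from 17.4 ± 0.893 to 8.98 ± 0.706 CPM (SD, n = 3 each), a log2 change of -0.95 (edgeR adjusted p = 4.50e-06). CSF3 (-0.76, edgeR adjusted p = 0.0152), C15orf48 (-0.73, adjusted p = 0.0161) and CXCL3 (-0.65, adjusted p = 0.0113) completed the set. Every RBM24 library lay below every control library for all of them, as the naming rule required. The call of CSF3 ended without control library 1 (adjusted p = 0.0545), RBM24 library 1 (0.0621) or RBM24 library 2 (0.0603), that of C15orf48 without RBM24 library 1 (0.0584) or 2 (0.0827), and that of CXCL3 without RBM24 library 2 (0.0624). DESeq2 gave adjusted p of 0.0529 for CCL20, 0.0690 for S100A8, 0.0645 for CSF3, 0.145 for C15orf48 and 0.0690 for CXCL3.

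Of 31 tested pro-apoptotic genes, TNFSF10, which encodes the death receptor ligand TRAIL, fell from 93.5 ± 12.6 to 70.4 ± 6.83 CPM (SD, n = 3 each; log2 change -0.41, SE 0.0824, edgeR adjusted p = 0.0173), and the other 30 did not pass. Adjusted over the list alone, 1 gene was higher and 3 were lower: the BH3-only genes BBC3 (-0.39, adjusted p over all genes 0.0875) and BID (-0.21, 0.127) joined TNFSF10, and DIABLO, which encodes an inhibitor of IAP proteins, had a log2 change of 0.66 (0.0904). The counted DIABLO entry held 1.22 CPM on average and overlaps, on the same strand, an entry with 62.1, so its value is uncertain. The pore-forming BAX (-0.02, adjusted p = 0.926) did not pass. The list's median log2 change was -0.04 (camera, adjusted p = 0.213; adjusted p = 0.708 with an estimated correlation). Without control library 3 the median was -0.07 and the list passed (adjusted p = 0.0491), and without control library 2 the median was 0.01. Over all alternatives the adjusted p ranged from 0.0491 to 0.783. The call of TNFSF10 ended without RBM24 library 1 (adjusted p = 0.0884) or 2 (0.0912) and by DESeq2 (0.0834).

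Among 17 anti-apoptotic genes, BCL2L1, which encodes BCL-XL, rose from 76.3 ± 5.57 to 95.6 ± 2.61 CPM (SD, n = 3 each; log2 change 0.33, SE 0.0559, edgeR adjusted p = 0.00665). BIRC5, which encodes survivin, an inhibitor of apoptosis protein that also acts in mitosis, rose from 175 ± 5.57 to 212 ± 12.1 (SD, n = 3 each; log2 change 0.28, adjusted p = 0.0133), and in both genes all RBM24 libraries lay above all control libraries. Adjusted over the list alone, 2 genes were higher and 3 lower. The lower ones were BCL2A1 (-0.74), TNFAIP3 (-0.33) and CFLAR (-0.24), with adjusted p over all genes of 0.0795, 0.0892 and 0.101 (CFLAR was named after its value was seen). BCL2 (-0.06, adjusted p = 0.893) and MCL1 (-0.08, adjusted p = 0.639) did not pass. The list as a whole did not pass (median log2 change -0.04; camera, adjusted p = 0.793; adjusted p = 0.900 with an estimated correlation). The call of BIRC5 ended without RBM24 library 1 (adjusted p = 0.0951) or 2 (0.0942), and with limma on log2(FPKM + 1) BCL2L1 had an adjusted p of 0.0985.

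Inflammatory genes controlled by NF-kB were lower as a group in camera with its preset correlation (adjusted p = 1.27e-31). They did not pass otherwise (adjusted p = 0.254 with an estimated correlation; fry, adjusted p = 0.216). All 28 tested members had negative log2 changes, with a median of -0.47, and 15 fell at the all-gene threshold. Adjusted over the list alone, 21 fell and 0 rose. Beside the chemokines above, IL1A changed by -0.60 (edgeR adjusted p = 0.0161), IL1B by -0.47 (adjusted p = 0.0307), CXCL1 by -0.55 (adjusted p = 0.0318), the superoxide dismutase gene SOD2 by -0.46 (adjusted p = 0.0181), the adhesion molecule ICAM1 by -0.37 (adjusted p = 0.0159) and the inhibitor of NF-kB NFKBIA by -0.30 (adjusted p = 0.0418). CXCL8 (-0.58, adjusted p = 0.0795), TNF (-0.32, adjusted p = 0.275) and IL6 (-0.13, adjusted p = 0.629) did not pass. These genes beside the 5 above were named after their values were seen. CXCL1, CXCL2 and CXCL3 are close paralogs, so reads may be split among them. Control library 1, which stood apart on the main axis, had the highest level: the list's median against the mean of all libraries was 0.47, 0.27 and -0.02 in control libraries 1 to 3 and -0.34, -0.23 and -0.05 in RBM24 libraries 1 to 3, so that the third library of each group differed by less than the others. The number of members that fell was 9 without control library 1, 6 without RBM24 library 1 and 3 without RBM24 library 2. It was 7 by DESeq2, 16 by limma-voom and 0 on the FPKM values by limma.

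Antigen presentation genes were also lower, with negative log2 changes in 19 of 20 and a median of -0.15 (camera, adjusted p = 5.91e-11; adjusted p = 0.247 with an estimated correlation). The MHC class II genes HLA-DRA (-0.52, edgeR adjusted p = 0.00687), HLA-DRB1 (-0.51, adjusted p = 0.0111) and HLA-DMA (-0.34, adjusted p = 0.0464) fell, as did the peptide-trimming aminopeptidase gene ERAP2 (-0.27, adjusted p = 0.0158). The other 16 did not pass, and adjusted over the list alone 1 was higher and 10 were lower. HLA-DMA lost its call without any of 5 libraries (all but control 1; adjusted p = 0.0624 to 0.198), HLA-DRB1 without RBM24 library 2 (0.0692) and ERAP2 without RBM24 library 1 (0.0876) or 2 (0.106), and the number that fell was 2 and 1 without RBM24 libraries 1 and 2, 7 by DESeq2 and 0 or 1 on the FPKM values.

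Interferon-stimulated genes went both ways. IFI27, from 71.8 ± 11.6 to 130 ± 19.2 CPM (SD, n = 3 each), IFI6 (log2 change 0.51, edgeR adjusted p = 0.00131) and the 2'-5'-oligoadenylate synthetase gene OAS3 (0.36, adjusted p = 0.0317) rose, and its relative OASL fell (-0.31, adjusted p = 0.0152). The remaining 31 of 35 did not pass, and adjusted over the list alone 6 were higher and 3 lower. The list's median was 0.06 (camera, adjusted p = 0.0889; adjusted p = 0.809 with an estimated correlation). It passed without control library 1 (adjusted p = 3.27e-04), RBM24 library 1 (1.65e-07) or RBM24 library 2 (0.0214), with total-count scaling (0.0327) and with no filter (0.0385). Its median was -0.01 without RBM24 library 3. Over all alternatives the adjusted p ranged from 1.65e-07 to 0.606. OAS3 lost its call without any of 4 libraries (control 2 and 3, RBM24 2 and 3; adjusted p = 0.0788 to 0.0947) and by DESeq2 (0.141), and OASL without RBM24 library 1 (0.0951) or 2 (0.107).

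**Figure D2:**
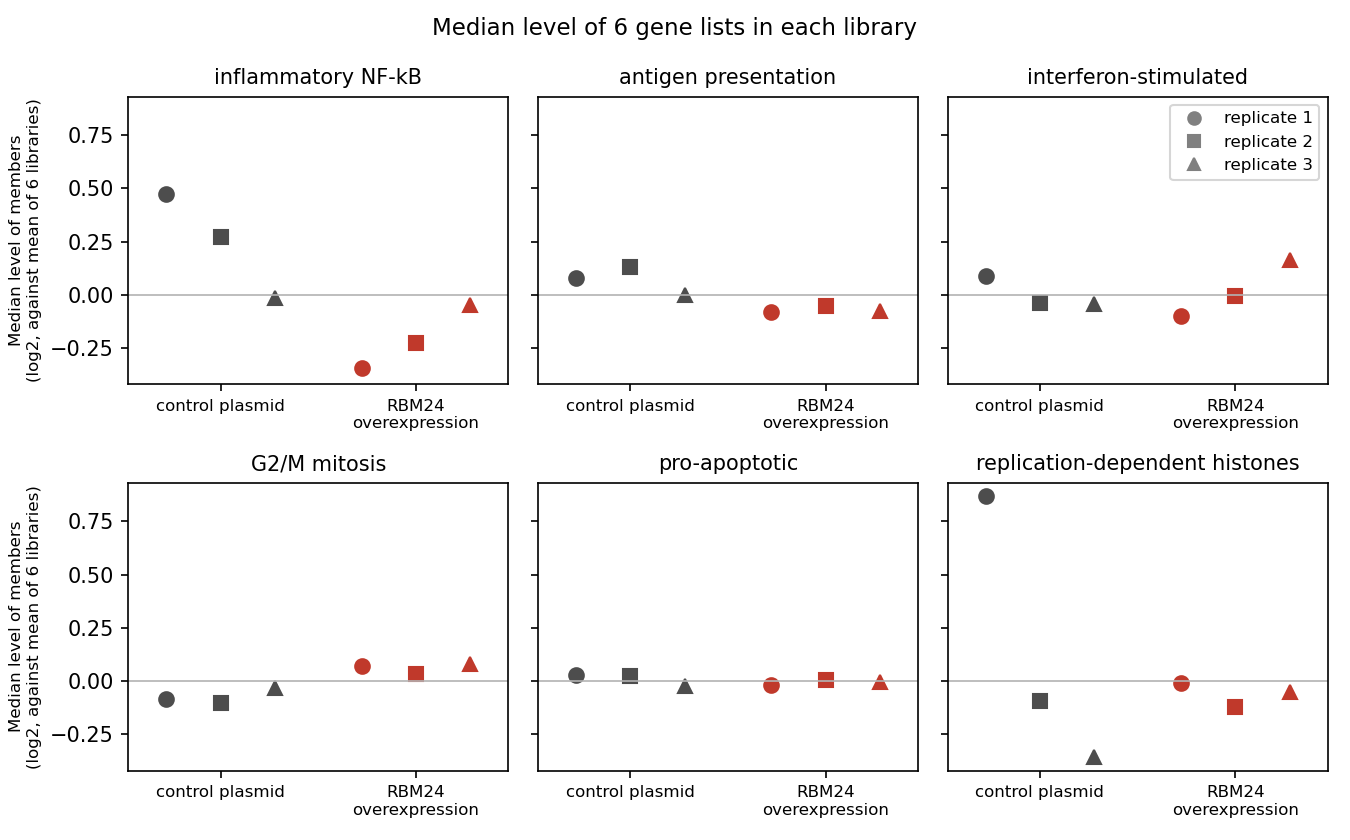
Median log2 level of the members of 6 gene lists in each library, relative to the mean of the 6 libraries, with control plasmid libraries in grey, RBM24 libraries in red and shapes for the replicate number. The inflammatory list lay between -0.02 and 0.47 in the control libraries and between -0.34 and -0.05 in the RBM24 libraries, and the histone list stood at 0.87 in control library 1.

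Mitotic genes were slightly higher with RBM24. Of 23 genes of the G2 and M phases, 22 had positive log2 changes with a median of 0.12 (camera, adjusted p = 2.01e-11; adjusted p = 0.153 with an estimated correlation). The 4 that rose were the Aurora kinase gene AURKB (0.28, edgeR adjusted p = 0.00902), the ubiquitin-conjugating enzyme gene UBE2C (0.25, adjusted p = 0.0183), the centromeric histone gene CENPA (0.25, adjusted p = 0.0353) and the kinesin gene KIF20A (0.22, adjusted p = 0.0356). Adjusted over the list alone, 10 were higher and 0 lower. Without RBM24 library 1 or 2, 0 of the 23 genes passed in edgeR (adjusted p = 0.0553 to 0.238 for these 4), without control library 1 or RBM24 library 3 the number was 2, and DESeq2 called 8. CENPA and KIF20A also lost their calls without control library 1 (0.0858 and 0.115) or 2 (0.0555 and 0.0565) or RBM24 library 3 (0.0533 and 0.0786), and UBE2C without control library 3 (0.0528). CENPA, at 38.3 CPM on average, overlaps SLC35F6 on the same strand, which has 61.2, so the value of CENPA is uncertain. The same holds for the list member NUSAP1, at 0.182 CPM, which overlaps an entry with 151.

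Of 24 genes of the G1/S transition and DNA replication, CCNE1, which encodes cyclin E1, rose (0.36, edgeR adjusted p = 0.00958; higher in all 3 RBM24 libraries) and the other 23 did not pass. Adjusted over the list alone, 2 were higher, CCNE1 and the thymidylate synthase gene TYMS (0.16, adjusted p over all genes 0.107). The list's median of 0.03 did not pass in camera (adjusted p = 0.0620; adjusted p = 0.434 with an estimated correlation), but did under 11 of 20 alternatives, among which the lowest and highest adjusted p were 2.04e-04 and 0.140; leaving out control library 2 gave 0.0485 and leaving out RBM24 library 2 gave 0.0416. CCNE1 lost its call without RBM24 library 1 (adjusted p = 0.0636). The replication-dependent histone genes followed control library 1, where their median level was 0.87, against -0.36 to -0.01 in the other 5 libraries. Of 26 tested, H2BC11 rose and the other 25 did not pass (adjusted over the list alone, 1 higher and 0 lower), and the list's median was -0.17, its mean -0.42 (camera, adjusted p = 0.154; adjusted p = 0.809 with an estimated correlation). Without control library 1 the histone list was higher, at a median of 0.13 (adjusted p = 0.0199). Without control library 2 or 3 it was lower, at -0.41 (adjusted p = 0.00766) and -0.55 (adjusted p = 6.77e-05), and over all alternatives the adjusted p ranged from 6.77e-05 to 0.469. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 (-0.04, edgeR adjusted p = 0.905), cyclin D1 (CCND1, 0.05, adjusted p = 0.760), MYC (-0.12, adjusted p = 0.276) and EGFR (-0.00, adjusted p = 0.995) did not pass.

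Squamous identity genes were tested in 2 lists. Among 18 basal keratinocyte genes, the keratin gene KRT15 (-0.30, edgeR adjusted p = 0.0131) and the nerve growth factor receptor gene NGFR (-0.35, adjusted p = 0.0201) fell, over all genes as well as adjusted over the list alone (0 higher, 2 lower). TP63, the master regulator of basal squamous cells, had a log2 change of -0.07 (adjusted p = 0.621), and the list's median was 0.05 (camera, adjusted p = 0.809; adjusted p = 0.900 with an estimated correlation). Among 14 differentiation genes, S100A8 and its partner S100A9 (-0.60, adjusted p = 0.00312) fell, and adjusted over the list alone 1 was higher and 4 were lower. That list had a positive median (0.03) and a negative mean (-0.10), and camera's direction was lower (adjusted p = 0.143; adjusted p = 0.708 with an estimated correlation). It passed without control library 3 (adjusted p = 2.14e-05), RBM24 library 1 (0.0265) or RBM24 library 2 (0.0368, median -0.08), within a range of 2.14e-05 to 0.852 over all alternatives. NGFR lost its call without control library 3 (0.0541), RBM24 library 1 (0.161) or RBM24 library 2 (0.118), and KRT15 without RBM24 library 1 (0.0951).

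Of 19 epithelial adhesion genes 0 passed in edgeR, with 3 at an unadjusted p under 0.05 (1 higher, 2 lower), 1 higher by DESeq2 and 0 by limma-voom; adjusted over the list alone the count was 0. E-cadherin (CDH1) had a log2 change of 0.17 (edgeR adjusted p = 0.106), and the list's median was -0.00, or 0.03 with total-count scaling (camera, adjusted p = 0.899; adjusted p = 0.915 with an estimated correlation). Among 23 mesenchymal and invasion genes, MMP1, SNAI1 and the adhesion molecule gene L1CAM (0.38, adjusted p = 0.0158) rose and the urokinase gene PLAU fell (-0.39, adjusted p = 0.00893), while adjusted over the list alone 3 were higher and 2 lower. The median (-0.06) and the mean (0.11) of that list differed in sign, and camera's direction was higher (adjusted p = 0.537; adjusted p = 0.809 with an estimated correlation). PLAU lost its call without RBM24 library 1 (adjusted p = 0.0551) or 2 (0.0664), and L1CAM without RBM24 library 2 (0.0734) or 3 (0.0584).

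Targets of NRF2, the regulator of the antioxidant response, were higher in camera with its preset correlation (adjusted p = 1.46e-12; adjusted p = 0.153 with an estimated correlation). AKR1C1, AKR1C2, AKR1C3 (0.54, edgeR adjusted p = 0.00739), HMOX1 and the quinone reductase gene NQO1 (0.25, adjusted p = 0.0159; named after its value was seen) rose, each with all RBM24 libraries above all control libraries, and the other 15 of 20 did not pass. Adjusted over the list alone, 6 were higher and 0 lower. The median was 0.07 and the mean 0.30, with AKR1C1 and AKR1C2 far above the rest. With limma on log2(FPKM + 1) and no filter the number that rose was 2, and without RBM24 library 1 or 2 it was 4. Immediate early genes split: FOS (0.93, adjusted p = 4.73e-04), CCN2 (0.47, adjusted p = 4.24e-04), IER2 (0.27, adjusted p = 0.0115) and DUSP5 (0.23, adjusted p = 0.0303) rose, while 10 of 20 members had negative log2 changes and adjusted over the list alone 7 were higher and 3 lower. That list's median was 0.03 and its mean 0.06 (camera, adjusted p = 0.00804; adjusted p = 0.696 with an estimated correlation). It did not pass without control library 3 (adjusted p = 0.236, median -0.06) or RBM24 library 3 (0.200, median -0.07) or on the FPKM values (0.0710 to 0.124), within a range of 1.70e-04 to 0.236 over all alternatives. Without RBM24 library 1 or 2, 2 of its members rose. IER2 lost its call without RBM24 library 1 (0.0727) or 2 (0.104), and DUSP5 without any of 4 libraries (all but control 1 and 2; adjusted p = 0.0843 to 0.195).

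Other stress and metabolic lists had small median changes, and only some of them passed camera with its preset correlation. Of 25 ATF4 stress response genes the pseudokinase gene TRIB3 rose (0.28, edgeR adjusted p = 0.0264), also adjusted over the list alone (1 higher, 0 lower), and the median was 0.02 (camera, adjusted p = 0.399; adjusted p = 0.753 with an estimated correlation). TRIB3 lost its call without control library 1 (adjusted p = 0.0591) or 3 (0.0747) or RBM24 library 1 (0.203) or 2 (0.116). Of 19 ER chaperone and quality control genes the transcription factor gene XBP1 fell (-0.32, adjusted p = 0.0149), also adjusted over the list alone (0 higher, 1 lower), and 17 had negative log2 changes with a median of -0.06 (camera, adjusted p = 0.00804; adjusted p = 0.660 with an estimated correlation). Without control library 1 that list did not pass (median -0.04, adjusted p = 0.115, range over all alternatives 5.83e-04 to 0.115), and XBP1 lost its call without RBM24 library 1 (0.0861) or 2 (0.0734). Heat shock genes had a median of 0.07 (camera, adjusted p = 0.0478; adjusted p = 0.693 with an estimated correlation); 0 of 15 passed in edgeR, with 3 higher at an unadjusted p under 0.05, 1 higher by DESeq2, 0 by limma-voom and 2 higher adjusted over the list alone, HSPA1A (0.20) and CHORDC1 (0.19). HSPA1A and HSPA1B are near-identical, so their counts are uncertain. The heat shock list did not pass without control library 3 (adjusted p = 0.259), RBM24 library 1 (0.116) or RBM24 library 3 (0.0699), nor among protein-coding genes alone (0.0834), within a range of 0.00152 to 0.259, and without control library 2 its median was 0.03.

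Cholesterol synthesis genes had negative log2 changes in 17 of 21, with a median of -0.10 (camera, adjusted p = 3.04e-04; adjusted p = 0.434 with an estimated correlation). 0 of them passed in edgeR, DESeq2 or limma-voom or adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05, among them HMGCS1 (-0.21, edgeR adjusted p = 0.203). Without control library 1 the median was -0.05 and the list still passed (adjusted p = 0.0118). Of 24 hypoxia and glycolysis genes 0 passed in edgeR, DESeq2 or limma-voom or adjusted over the list alone, with 3 higher and 3 lower at an unadjusted p under 0.05 and a median of -0.04 (camera, adjusted p = 0.399; adjusted p = 0.809 with an estimated correlation); without control library 3 the median was -0.08 and the list passed (adjusted p = 0.0399, range 0.0399 to 0.933).

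RBM24 acts on splicing and on muscle transcripts elsewhere, so both gene groups were followed. Of 50 splicing regulator genes 0 passed in edgeR or limma-voom or adjusted over the list alone. DESeq2 called 1 lower, and 2 were higher and 3 lower at an unadjusted p under 0.05. The cold-inducible RBM3 had the smallest p (-0.19, edgeR adjusted p = 0.0766), and the related RBM38 had a log2 change of -0.03 (adjusted p = 0.855). The median of this list was -0.02, or 0.01 with total-count scaling (camera, adjusted p = 0.399; adjusted p = 0.814 with an estimated correlation). Of 25 muscle genes 10 were tested, most at very low levels, with a median of 0.29 (camera, adjusted p = 0.00146; adjusted p = 0.254 with an estimated correlation). The giant sarcomeric gene NEB rose (2.01, adjusted p = 0.0159) from 0.0937 ± 0.0292 to 0.378 ± 0.0875 CPM (SD, n = 3 each), and adjusted over the list alone 3 were higher, with ACTA1 (1.47, adjusted p over all genes 0.0919) and MYH3 (0.51, 0.0620), and 0 lower. The muscle list did not pass with no filter (adjusted p = 0.0704, median 0.07), with a mean count of at least 50 (0.0995, median 0.09) or on unfiltered FPKM values (0.129, median 0.01), within a range of 5.25e-04 to 0.129. NEB lost its call without control library 2 (0.0524) or 3 (0.0519) or RBM24 library 1 (0.0951) or 3 (0.0507). The tested TNNT2, at 0.259 CPM on average, overlaps LAD1 on the same strand, which has 63.8, so the value of TNNT2 is uncertain.

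**Figure D3:**
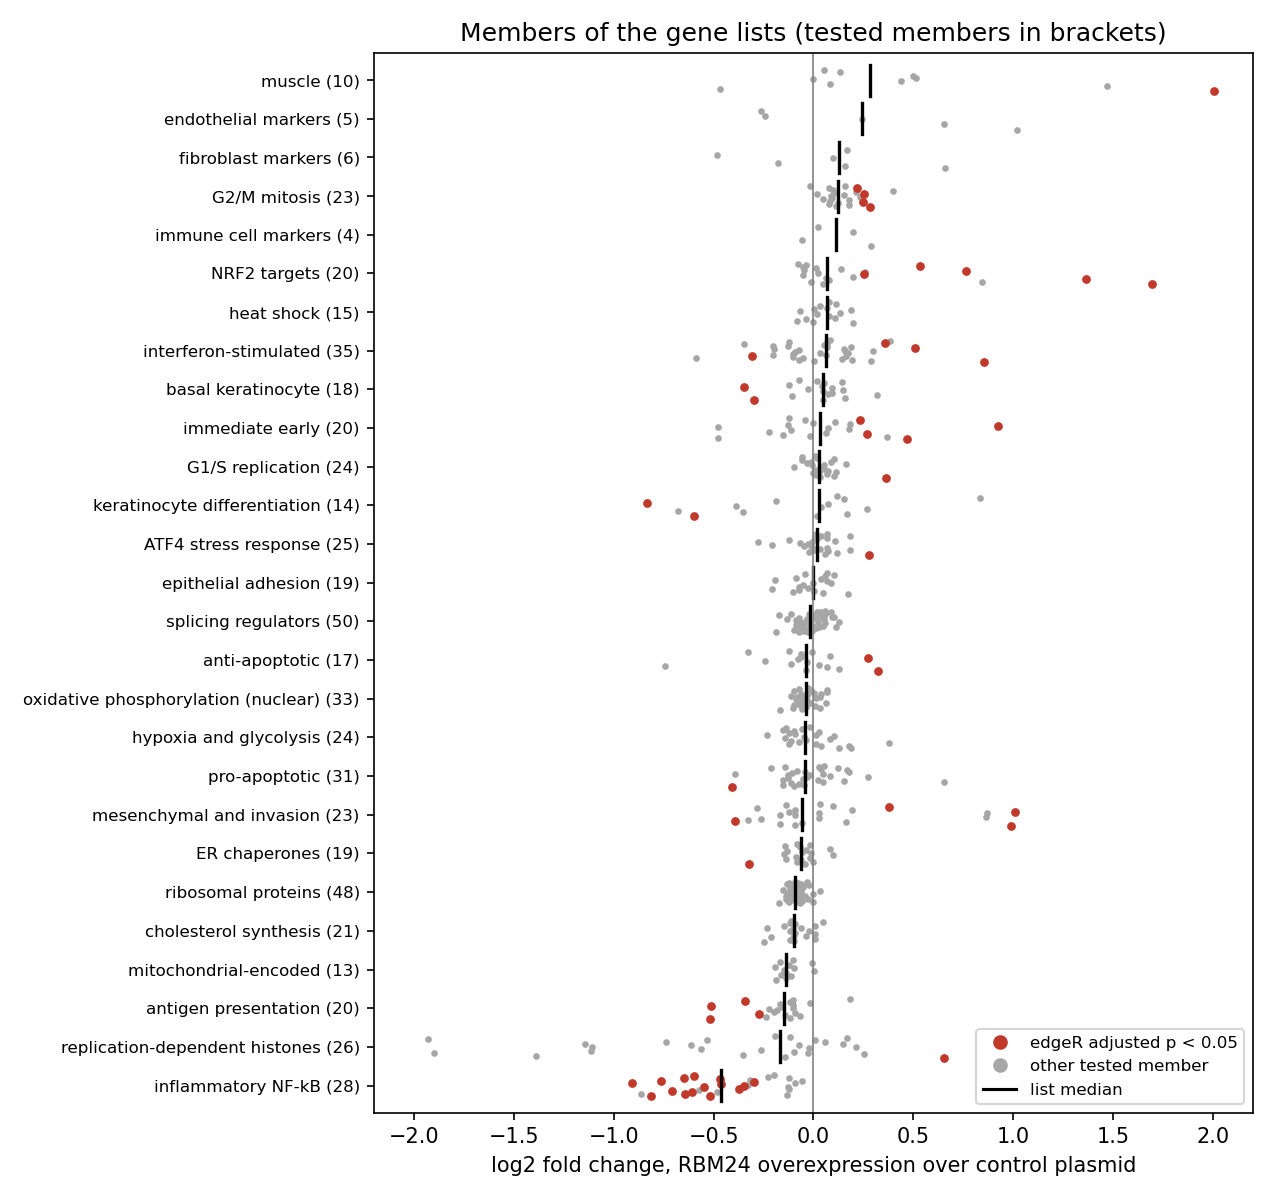
log2 fold change, RBM24 overexpression over control plasmid, of each tested member of the gene lists described in the text, with the number tested in brackets. Red points passed the edgeR test at an adjusted p under 0.05, grey points did not, and black lines are list medians, from -0.47 for inflammatory NF-kB genes to 0.29 for muscle genes.

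Among markers of other cell types, 6 of 13 fibroblast, 4 of 14 immune and 5 of 10 endothelial ones passed the filter on low counts. The monocyte marker CD14 and the endothelial CDH5 stood at 19.0 ± 1.43 and 10.2 ± 1.21 CPM (SD, n = 3 each) in the control libraries. Of the fibroblast, immune and endothelial markers 6, 4 and 5 were tested, with medians of 0.13, 0.11 and 0.25 (camera, adjusted p = 0.526, 0.537 and 0.537; adjusted p = 0.753 for each with an estimated correlation). None of the 15 passed in edgeR, DESeq2 or limma-voom. At an unadjusted p under 0.05 the fibroblast gene COL1A2 (0.66) and the endothelial ROBO4 (1.02) were higher and CDH5 (-0.24) lower, and the same genes were the ones found adjusted over the list alone. Mitochondrial transcripts took 8.13%, 8.40% and 8.05% of counts in the control libraries and 7.26%, 7.75% and 7.49% in the RBM24 libraries. The 13 mitochondrially encoded genes had a median log2 change of -0.14 (camera, adjusted p = 2.14e-05; adjusted p = 0.496 with an estimated correlation), and 0 passed in edgeR or limma-voom or adjusted over the list alone, with 7 lower at an unadjusted p under 0.05 and 2 lower by DESeq2. The 33 nuclear genes of oxidative phosphorylation had a median of -0.04 (camera, adjusted p = 0.122; adjusted p = 0.809 with an estimated correlation), and 0 passed in edgeR, DESeq2 or limma-voom or adjusted over the list alone, with 2 lower at an unadjusted p under 0.05. That list passed without control library 3 and without RBM24 library 1, where its median was -0.12 and -0.10 (adjusted p = 1.21e-05 and 1.04e-04), and with no filter (adjusted p = 0.0416), within a range of 1.21e-05 to 0.928. Ribosomal protein genes had a median of -0.09 over 48 members (camera, adjusted p = 1.79e-06; adjusted p = 0.718 with an estimated correlation), and 0 passed in edgeR, DESeq2 or limma-voom or adjusted over the list alone, with 5 lower at an unadjusted p under 0.05. Its median was -0.15 without control library 3, -0.14 without RBM24 library 1, -0.06 without control library 1 and -0.05 without RBM24 library 3, and it passed in each (adjusted p = 9.20e-17 to 0.0430).

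In all, 11 of the 28 lists passed camera's test with the preset correlation, 5 of them higher and 6 lower, and 0 passed with an estimated correlation, where 5 had an unadjusted p under 0.05. fry's test of movement in 1 direction, which compares no list with other genes, passed for 2 lists, the mitotic genes and the NRF2 targets (adjusted p = 0.0250 for each), and its test of change in either direction for 17.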

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

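Protein-coding genes only was the 1 alternative chosen after the results were seen. The RBM24 log2 fold change kept its direction and its call under all 19 alternatives tried, and was 5.20 to 5.50 without each library in turn and 4.24 with limma on log2(FPKM + 1), where the pseudocount of 1 exceeds its control level. The replicate numbers did not pair the samples (correlations within numbers of 0.00724, 0.0555 and -0.00039); with the replicate block, 158 genes were higher and 135 lower, and 1 of the named calls was lost.

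The counts of genes moved by over 1.5 times under these alternatives: 28 higher and 4 lower at a log2 fold change of at least 1, 59 and 26 at an adjusted p under 0.01, 305 and 341 with no low-count filter, 46 and 4 with limma on log2(FPKM + 1), 57 and 5 on log2(FPKM + 0.1), and 15 and 4 on log2(FPKM + 1) with no filter. Stricter thresholds call fewer genes by construction; for the others the cause was not tested. Without each library in turn, 61 to 171 genes were higher and 29 to 198 lower, with fewer samples in each fit. The remaining alternatives stayed within 1.5 times: 140 to 223 higher and 106 to 160 lower.

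The pro-apoptotic median lay between -0.0731 and 0.0122 without each library, and the list passed without control library 3 (-0.0731, adjusted p = 0.0491). The anti-apoptotic list passed under none (adjusted p = 0.198 to 0.971). The histone list turned from lower to higher without control library 1 (0.125, adjusted p = 0.0199) and stood at -0.552 without control library 3; the cause was not tested beyond the tests given under the other observations. Of the 11 lists that passed, 7 did so under all 20 alternatives on the data: antigen presentation, inflammatory, G2/M, cholesterol synthesis, NRF2, mitochondrial-encoded and ribosomal proteins. All these keep the preset correlation, and 0 of the 11 passed with an estimated one (lowest adjusted p = 0.153). Of 53 named calls besides RBM24, 5 held under all 19 alternative fits followed for them (AKR1C1, GADD45B, HMOX1, CDKN2D and DHRS9). These fits leave out the stricter thresholds and the protein-coding fit. Without at least 1 library, 25 calls were lost (edgeR adjusted p = 0.0507 to 0.258), and none changed sign. Thinning to the smallest library left 151 higher and 118 lower; the totals differ too little for this to show what depth limits.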

Other observations

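The genes in these opening paragraphs were chosen after their values were seen, and no test of enrichment was run on them. CSF1, the macrophage growth factor gene, changed by -0.49 on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.00221), the interferon regulatory factor gene IRF1 by -0.27 (adjusted p = 0.0236), the complement factor gene CFB by -0.55 (adjusted p = 0.0159) and the lipocalin gene LCN2 by -0.25 (adjusted p = 0.0303). The kinase genes RIPK2 (-0.34, adjusted p = 0.0110) and IRAK2 (-0.36, adjusted p = 0.0219), which act downstream of pattern recognition receptors, and the receptor gene TNFRSF9 (-0.52, adjusted p = 0.0311) fell as well. So did SOCS1 (-0.45, adjusted p = 0.0466) and ZC3H12A (-0.31, adjusted p = 0.0301), which restrain cytokine signalling. TNFSF14, a ligand of the TNF family, rose (0.93, adjusted p = 0.00120). The glutathione peroxidase gene GPX2 (0.68, adjusted p = 0.0242) and the epoxide hydrolase gene EPHX1 (0.29, adjusted p = 0.0231) rose.

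The naming rule left out genes with low levels, and the largest fold changes lay there: 11 genes with a mean log2 CPM under 2 rose at least 4-fold and 1 fell, against 0 above that level besides RBM24. Some of those that rose had very few control counts, such as HIGD2AP1 (1, 0 and 0), AZU1 (2, 1 and 3) and SYT11 (1, 1 and 4). The 1 that fell was the processed pseudogene RPS3AP5, with 161, 112 and 11 control counts against 12, 13 and 8. Its libraries overlapped between the groups, and its call rested on control libraries 1 and 2. The germ cell gene TEX14 rose from 31, 38 and 58 counts to 291, 208 and 285 (log2 change 2.52, edgeR adjusted p = 2.00e-07), and ID2, an inhibitor of basic helix-loop-helix factors, from 14, 5 and 18 to 105, 76 and 96 (2.79, adjusted p = 2.76e-05). GADD45G, a relative of GADD45B, rose by 1.11 (adjusted p = 0.00484). The processed pseudogene PPIAP22 had 2475, 2425 and 637 counts in the control libraries against 721, 599 and 626 (adjusted p = 0.0190), so its call rested on control libraries 1 and 2.

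The inflammatory, NRF2, histone and YAP patterns followed below were picked after the results above were seen. Of their tests, that of the inflammatory list without control library 1 was chosen only after its own result was seen. The inflammatory list was lower with RBM24 in camera with the preset correlation (adjusted p = 0.254 with an estimated correlation) and highest in control library 1. Without that library its median was -0.326, so control library 1 alone was not the whole cause. Of 10000 random lists matched on GC content, length and expression, 100% had a median above the list's, the random medians lying between -0.0842 and 0.0562. Random members were drawn separately, so these lists lack the correlation among the inflammatory genes (estimated at 0.785). The comparison thus bears on GC content, length and expression, and not on the spread between libraries. Effects of handling, or of the RBM24 plasmid beyond those of the control plasmid, stay open for the inflammatory genes. A lower NF-kB activity with RBM24 may be one biological explanation, which was not tested.

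The NRF2 targets were higher with RBM24 in camera with the preset correlation (adjusted p = 0.153 with an estimated correlation). Here the mean was compared instead of the median. Of 10000 random lists matched in the same way, 100% had a mean below the list's, the random means lying between -0.150 and 0.132. These random lists also lack the correlation among the list's members, and the list's median of 0.07 was not compared. Much of the mean of 0.30 came from the AKR1 family, since the other 16 genes had a mean of 0.0974. No random lists were drawn for those 16. Without the AKR1 family members, whose reads can be shared, those 16 still passed with the preset correlation (camera, p = 0.00442; p = 0.120 with an estimated correlation), with HMOX1 and NQO1 called and a median of 0.04. GC content and length stay open for these 16. An NRF2 response to RBM24, or to stress beyond that caused by the control plasmid, could both give this, and the design does not separate them.

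Histone transcripts stood high in control library 1. More RNA without a poly(A) tail in that library is one candidate explanation. Its share of counts in small structured RNA genes was 7.19-fold the mean of the other 5 libraries, while its share in the listed histone genes was 1.19-fold. The S phase explanation stays open: the G1/S list stood at -0.0240 in control library 1, below control library 2 by 0.0133, which is less than the SD of 0.0266 of the other 5 libraries. The rule that a gap has to exceed that spread was set after the value was seen. By the rule set before, a level below that of another control library counted against more cells in S phase, so the changed rule left it open. Control library 1 also lay below the RBM24 libraries (0.0396, 0.00224 and 0.0280) and just above control library 3 (-0.0243). No biological explanation from the design was tested for a single library.

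One hypothesis came from ANKRD1 and CCN2, both targets of YAP, a transcriptional coactivator of growth: that YAP activity may be higher with RBM24. In a published signature of 22 YAP targets, 19 had positive log2 changes, with a median of 0.07 (camera, p = 5.52e-06; p = 0.0787 with an estimated correlation). AMOTL2, ANKRD1 and CCN2 rose and IGFBP3 fell (-0.22, edgeR adjusted p = 0.0264). The signature holds ANKRD1 and CCN2 themselves, so the test is not independent of what prompted it.

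The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05; the real split called 275 genes in edgeR and the highest other split 0, which makes 1 split with as many. At an unadjusted p under 0.05 the real split had 2330 genes, and the split with control libraries 1 and 3 and RBM24 library 3 on one side had more, 2405.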
